A study of Mus musculus with 2 samples.

How the data were processed

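Chromatin immunoprecipitation with sequencing (ChIP-seq) against histone H3 monomethylated at lysine 4 (H3K4me1) was carried out on mouse regulatory T cells described in the labels as having experienced inflammation. The data are 2 tables, 1 for each library. The labels give both libraries the same biological replicate number and the same donor, and number them as technical replicates 1 and 2, so they come from 1 biological sample. There is 1 group and no second condition, and neither an input library nor another histone mark was analysed here.

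Per the text deposited with each library, the authors made each table from that library's alignments to the mouse assembly mm10 and from 1 further file common to both libraries, and they list it as a quantification of enrichment. The aligner, the read filters, the treatment of duplicate reads and the counting tool are not given in the sources used here. As deposited, each table holds a running feature number and 1 whole number per feature, which was read as a count of reads without normalization. That reading came from the values: they were whole, started at 0 and had different totals in the 2 libraries. The common file was not used here, so the coordinates, widths and neighbouring genes of the features were not analysed, and no gene was assigned to a feature from its number. The sum of a table counts reads within the listed features and is not the sequencing depth of the library, which is also not given in the sources used here.

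The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The counts were used as deposited. The libraries were compared across all 33643 features by Pearson's r of log2(count + 1), by Spearman's rho and by the SD of the log2 ratio; features are not independent replicates, so no p-value was attached to these. To set the differences against counting noise, the summed count of each feature was held fixed and divided between the libraries at the ratio of their totals. The squared standardized difference from that division was averaged over the features (the chi-square statistic divided by their number) and compared with 1000 simulated binomial divisions, two-sided. Each feature was also tested with an exact two-sided binomial test with Benjamini-Hochberg adjustment over all features. These tests compare the 2 libraries, not conditions or animals. Because the labels give the libraries as technical replicates of 1 biological sample, they were counted as 1 sample and their counts were summed. Over the features as a whole they differed by no more than counting noise. Count models that need biological replicates were not fitted.

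The spread between features beyond counting noise was calculated as a coefficient of variation (CV), from the covariance of the 2 libraries' counts relative to their means. Steps in level along the feature number were sought in log2(summed count + 1) by seeded binary segmentation, with a minimum run of 50 features and a penalty of 100. Bootstrap intervals are 95% intervals from 1000 resamples of features, or of blocks of 200 consecutive features for the neighbour statistics, and cover the variation between features. Shares carry Wilson 95% intervals and counts carry exact Poisson 95% intervals. A count of 0 was read as allowing up to 3 counts. CPM values are counts scaled to the summed total of the listed features. The Wilson and Poisson intervals, the limits and the binomial tests cover counting error alone, because reads are not necessarily independent molecules.

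The per-feature test was tried on simulated data built from the observed counts of the 33643 features, with 200 features changed between technical replicates 1 and 2. The binomial test called 3 of 50 features changed 2-fold, 18 of 50 changed 4-fold, 38 of 50 changed 8-fold and 44 of 50 changed 16-fold, and 7 of 33443 unchanged features. The segmentation was tried on independent simulated levels, not on the observed counts, and placed both of 2 simulated steps at their exact positions. This does not show how well it finds shorter runs in the real counts. It found no step in 20 shuffles of the real counts. Shuffling removes any similarity of neighbouring features, so it does not show how often such similarity alone would pass the penalty.

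Before the data were examined, the design named the comparison of the 2 libraries, the location of the features relative to genes, their presence at 13 lists of T cell, other cell type and control genes, comparisons among these lists and a ranking of stitched loci. The gene lists, the location classes and the stitching need coordinates and were not analysed here. The rule for named items, fixed at the same time, took the 5 features with the highest mean count and the 2 features with the largest ratio in each direction; the parts of the rule that name genes could not be applied. Alternatives fixed in advance were other pseudocounts, other scalings and a restriction to features with counts above the median. The division of the feature list into parts, the comparison of the highest features and the neighbour statistics were chosen after the counts had been seen.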

Results

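H3K4me1, a histone mark typical of enhancers and of the flanks of promoters, was measured by ChIP-seq in regulatory T cells from a male mouse aged 6 months. The cells are labelled as having experienced inflammation, and the strain carries an inducible Cre recombinase at Foxp3, the gene of the lineage-defining transcription factor of regulatory T cells, together with a YFP reporter. How inflammation was brought about is not given in the sources used here. The data comprised 2 libraries, technical replicates 1 and 2 of 1 biological sample, each with a count for the same 33643 numbered features. Without a second condition, the design allows the 2 libraries to be compared with each other and the features to be compared within the sample. Gene names and positions were not analysed here, so the features are described by number and count.

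Almost every feature carried reads of the H3K4me1 libraries. A count above 0 is not by itself enrichment, because no input and no feature widths were analysed. How the list of features was made was not examined either. A count above 0 was present in both libraries at 33278 features, which is 98.9% of the list, and 18 features were at 0 in both. The median feature held 14 reads in technical replicate 1 and 9 reads in technical replicate 2. The listed features together held 538802 reads in technical replicate 1 and 346895 in technical replicate 2, a ratio of 1.55. The share of features at 0 was 0.256% (Wilson 95% interval 0.207% to 0.316%) in the larger library and 0.883% (0.788% to 0.989%) in the smaller one. A feature at 0 in both libraries can still have a level of up to 3.39 CPM (counts scaled to the total of the listed features in both libraries), the limit that a count of 0 allows.

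The question put to the pair was how far 2 libraries of the same biological sample give the same counts. At which step the technical replicates were divided was not examined here, so their agreement need not cover the immunoprecipitation. They ranked the features alike, with a Spearman's rho of 0.769 (bootstrap 95% interval 0.764 to 0.773) and a Pearson's r of 0.759 (0.754 to 0.763) for log2(count + 1) across the features. Of the 15876 features above the median of technical replicate 2, 12494 were also above the median of technical replicate 1, against 7704 for independent lists. Dividing the summed counts at random between the libraries gave a simulated mean Pearson's r of 0.756 (95% range 0.752 to 0.759), so the observed correlation was not below what counting noise alone gives. The log2 ratio between the libraries had an SD of 0.634 across features, against 0.639 (0.633 to 0.645) in the simulated divisions.

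No feature differed between the libraries in the exact binomial test after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.854. At an unadjusted p under 0.05 there were 1147 features, fewer than the 1170 to 1317 found in 20 simulated divisions, and Fisher's exact test also gave 0 features after adjustment. The chi-square statistic over the 33625 features with a count was 32761 on 33624 degrees of freedom. The corresponding mean squared standardized difference of 0.974 lay below the simulated 95% range of 0.986 to 1.01 and below the lowest of the 1000 simulated values, 0.976. The libraries therefore differed by less than the sampling noise over the list as a whole. They were counted as 1 sample because they are technical replicates, whatever their agreement. No other pair of libraries was analysed here to set beside this one. Differences of 2-fold at single features were rarely detectable at this depth, since 3 of 50 such simulated changes were called.

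**Figure D1:**
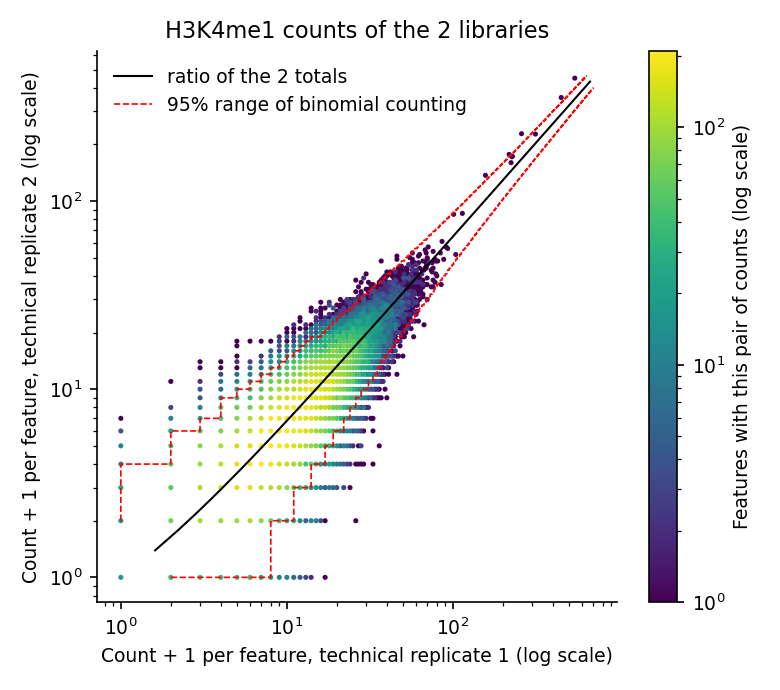
Count + 1 per feature in technical replicate 1 (x axis, log scale) against technical replicate 2 (y axis, log scale), with colour for the number of features at each pair of counts. The black line is the ratio of the totals, and the red dashed lines enclose 95% of binomial divisions. Most features lie within the dashed lines, and the few features with the highest counts lie on the side of technical replicate 2.

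The highest features were the exception to this agreement. The 12 features with a summed count of 150 or more had 43.9% of their reads in technical replicate 2 (Wilson 95% interval 42.6% to 45.3%), whereas that library held 39.2% of all counts. The difference was beyond counting noise (exact binomial p = 3.2e-12, adjusted p = 2.5e-11 over 8 count levels), and 11 of the 12 features lay in that direction. This test pools the reads of the 12 features and takes every read as independent. The cause of the difference was not tested. Without the highest feature the share was 43.6% (exact binomial p = 5.4e-09). The size of the difference depended on the cut: the share was 41.1% at 100 or more reads (75 features) and 44.2% at 200 or more (9 features). Features with at least 80 and fewer than 150 reads had 39.3% of their reads in technical replicate 2 (38.8% to 39.9%), which did not differ from the share over all counts beyond counting error. The count levels were set after the data had been seen.

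**Figure D2:**
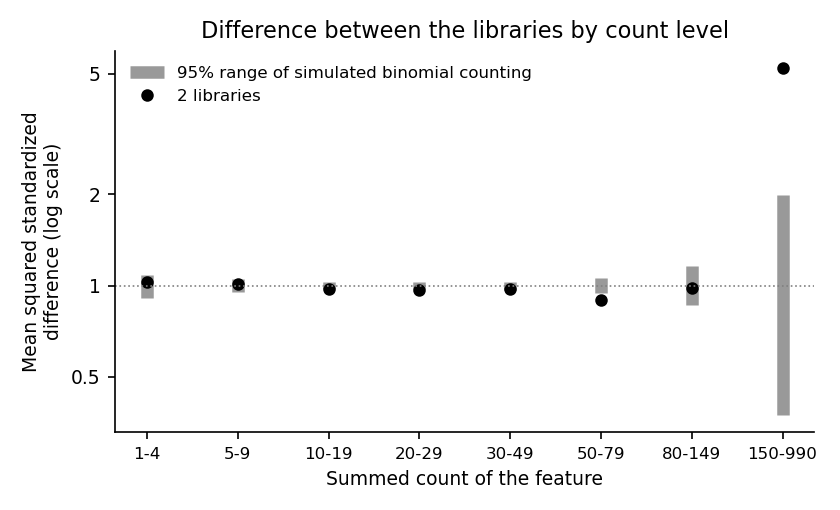
Mean squared standardized difference between the libraries (y axis, log scale) for features grouped by summed count (x axis). Points are the 2 libraries and grey bars are the 95% range of 1000 simulated binomial divisions; the point of the highest group, 5.22, lies above its range, and those of features with 20 to 29 reads, 0.971, and with 50 to 79 reads, 0.900, lie below.

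Read counts, which were not corrected for the width of a feature or for input, varied between features. The CV between features beyond counting noise was 0.659 (bootstrap 95% interval 0.597 to 0.737), and 0.565 (0.559 to 0.571) without the 12 highest features. The summed count was 15 at the lower quartile, 23 at the median and 34 at the upper quartile. The 99th percentile was 78 reads, 3.39 times the median, and the top 1% of features (337 features) held 3.92% of the counts. Counting alone sets the precision of a single feature: a summed count of 23 has an exact Poisson 95% interval of 14.6 to 34.5. The covariance of the 2 libraries' relative counts was also set against the variance of each library. It fell short of that variance by 7.96% in technical replicate 1 and by 21.8% in technical replicate 2. This shortfall measures the unshared variance only if both libraries have the same relative levels, which the 12 highest features do not. Without these features it was 16.1% and 22.5%.

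A few features stood far above the rest. Feature 6635 held 541 reads in technical replicate 1 and 449 in technical replicate 2, which is 43.0 times the median summed count. It was followed by feature 18076 with 448 and 354 reads, feature 4941 with 313 and 226, feature 12073 with 258 and 227, and feature 13152 with 227 and 172. On the CPM scale of both libraries together, feature 6635 stood at 1118 (Wilson 95% interval 1050 to 1190) and feature 13152 at 450.5 (408 to 497). At the other end, the largest ratios between the libraries were all at features with 16 reads or fewer. Feature 27042 had 16 reads in technical replicate 1 and 0 in technical replicate 2, and feature 27305 had 13 and 0. Feature 16744 had 0 reads in technical replicate 1 and 6 in technical replicate 2, and feature 13625 had 0 and 5. None of these 4 passed the exact binomial test after adjustment (adjusted p = 1 for each).

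The level also depended on the position of a feature in the numbered list, a comparison made after the data had been seen. Features 1 to 20108 had a mean summed count of 28.9 ± 18.9 (SD between features). From feature 20109 to feature 20633 the mean fell to 11.0 ± 6.3, which is 0.380 of the preceding level (bootstrap 95% interval 0.361 to 0.398). The features that followed returned to a lower plateau, with a mean of 23.8 ± 15.4 at features 20634 to 25827 and of 22.9 ± 16.2 at features 25939 to 33517, which are 0.825 (0.808 to 0.842) and 0.792 (0.779 to 0.807) of the level of the first part. Between these lay a run of 111 features, 25828 to 25938, with a mean of 12.6 ± 9.2, which is 0.527 (0.458 to 0.604) of the part before it. The last 126 features, 33518 to 33643, had a mean of 9.4 ± 7.2, which is 0.412 (0.361 to 0.469) of the part before them. The share of features with at least 10 reads was 94.6% in the first part, 54.7% in the first low-count run, 53.2% in the second and 39.7% in the third.

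Both libraries showed these levels separately. The first low-count run stood at 0.385 of the preceding part in technical replicate 1 and at 0.373 in technical replicate 2, and the third at 0.412 and 0.413. The second run stood at 0.499 and 0.572, and its boundaries were found in technical replicate 1 but not in technical replicate 2 alone at the same penalty. The boundaries at features 20108, 20633 and 33517 were found at the same feature in each library.

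**Figure D3:**
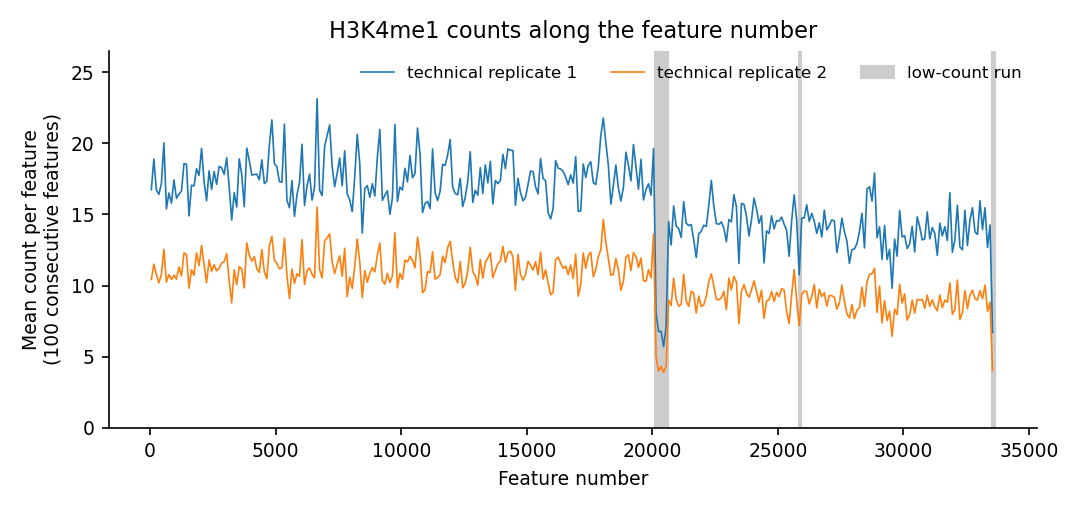
Mean count per feature (y axis, reads) in complete blocks of 100 consecutive features against feature number (x axis) for both technical replicates, with the 3 low-count runs shaded. Both lines drop in the shaded runs and lie lower after feature 20633 than before feature 20109.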

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

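The alternatives for the low-count runs, the long parts, the highest features, the per-feature tests, the mean squared difference and the spread between features were chosen after the data had been seen; the others were fixed before. Of 58 recomputed values, 42 kept their side of the threshold or stayed within the interval of the reported value, and 16 moved outside it. Some of the 42 could not move or repeat another value, so they are not independent checks. Spearman's rho does not depend on a pseudocount or on scaling, and a penalty of 60 gave the same boundaries. Technical replicate 1 also gave the boundaries of the summed counts. With counts from technical replicate 2, these repeat the values found without technical replicate 1. No value reversed and no test lost its call. Keeping only counts above the median left 16325 of the 33643 features in technical replicate 1 and 15876 in technical replicate 2, by construction, with 12494 in common. Pearson's r moved from 0.759 to 0.746 with a pseudocount of 0.5, to 0.743 without zeros and to 0.546 among features above the median summed count. Spearman's rho moved from 0.769 to 0.763 without zeros and to 0.481 above the median, where the range of levels is narrower by construction. The SD of the log2 ratio moved from 0.634 to 0.706 with the smaller pseudocount, to 0.719 without zeros, to 0.479 above the median, and to 0.615 when scaled by the median ratio or by totals (0.614913 and 0.614975). The spread between features fell from a CV of 0.659 to 0.565 without the 12 features of 150 or more reads, so the first value rests partly on them. It ranged from 0.640 to 0.677 when one technical replicate was left out. The level of the second long part relative to the first moved from 0.825 to 0.808 and that of the third from 0.792 to 0.731 with medians; the cause was not tested. Boundaries from technical replicate 2 do not separate the second low-count run, so they give no value for it or for the long parts on either side of it. Leaving out one technical replicate gave 0.373 to 0.385 for the first low-count run, 0.499 to 0.572 for the second and 0.412 to 0.413 for the third. A reciprocal overlap of the features and all alternatives for the gene lists, location classes and stitched loci need coordinates and were not run. No paired analysis was possible because there is 1 group. Depth limits single features: the median feature has 23 reads over both libraries.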

Other observations

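All tests of the low-count runs against a lower copy number, of the squared difference between the libraries with the count level and of the fall in similarity with distance were chosen after those results had been seen; the other tests had their outcomes written down before they were computed, except that features with 150 or more reads were left out of the windows for the CV afterwards, and with them the ranges of the windows were 0.435 to 1.26, 0.513 to 0.739 and 0.515 to 0.844, which also include the CVs of the 3 runs. The design has 1 group, so no biological explanation was tested against a second one.

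The 3 runs of low counts, at features 20109 to 20633, 25828 to 25938 and 33518 to 33643, each follow a long part. They raise the hypothesis that the numbered list joins ordered lists, 1 per run. Each list would end with features from a chromosome present once per cell, such as the X chromosome of a male. How many lists were joined was not tested. A copy number lowered to 0.5 as the whole cause predicts a ratio of 0.468 to 0.547 for the first run. The 0.380 found (0.361 to 0.398) lies below that range, which argues against copy number alone there. The interval treats features as independent, and the prediction takes the features of the run as otherwise like those before it. The second run, at 0.527, lies within its range of 0.424 to 0.576. For the third, at 0.412 (0.361 to 0.469) against 0.424 to 0.606, the interval is too wide to decide. A single factor applied equally to every feature of a run would leave the CV between features unchanged. The CVs beyond counting noise were 0.460, 0.657 and 0.653. They lay within the ranges of equally long windows of the preceding parts (0.435 to 0.540, 0.513 to 0.739 and 0.515 to 0.782). Their bootstrap intervals (0.406 to 0.509, 0.526 to 0.778 and 0.510 to 0.780) are about as wide as these ranges, so the test could hardly have failed. Weaker features without a common factor could also have such CVs. Whether a single factor accounts for any run therefore stays open. Narrower features and lower mappability, which need not act equally on every feature, could not be examined without coordinates.

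Neighbouring features had similar counts within the long parts, leaving out features with 150 or more reads, and this was not carried by the steps between parts: with part means removed, the correlation of summed counts at a distance of 1 feature was 0.0964, against -0.0114 to 0.0108 in shuffles within parts. Reads counted in both of 2 neighbours are argued against, because the covariance of neighbours within a library did not exceed that between the libraries (difference -0.00021 of the variance beyond counting noise, interval -0.0029 to 0.0022). The correlation beyond counting noise was 0.106 at a distance of 1 feature, 0.0744 at 2, 0.0318 at 5 and 0.0218 at 10, and was -0.00096 at 100. The difference between distances 1 and 100 was 0.107 (0.0869 to 0.128), which is consistent with a numbering that follows position along chromosomes, with nearby features alike in count. Another ordering by a property linked to the count could give the same decline, and the positions needed to separate them were not used here.

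The libraries differed by slightly less than independent counting predicts. The mean squared standardized difference was 0.974, against a simulated range of 0.986 to 1.01. Removal of reads at positions already seen could lower it. The test assumed that this lowering grows with the count, although the counts were not corrected for the width of a feature. Spearman's rho of the squared difference with the summed count was -0.0055 across features with at least 10 and fewer than 150 reads, within the simulated range of -0.0151 to 0.0090, and although a value within that range was first set to count against this explanation, that range includes values on both sides of 0 and the observed value is not outside it in either direction, so it stays open.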
